A study of Arabidopsis thaliana with 22 samples.

How the data were processed

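Gene expression was measured with 22 Affymetrix ATH1 arrays of Arabidopsis thaliana, 1 array per RNA sample, from whole 4-day-old seedlings of the accession Landsberg erecta (Ler). Per the labels' protocols, seeds were kept for 4 days in the cold and dark, received 3 h of white light, and were then grown for 4 days in darkness or under continuous red light. Dark-grown seedlings were collected directly or after 2 h of red light. The quintuple mutant phyABCDE lacks the phytochromes A to E, the plant's red and far-red light receptors, and the quadruple mutant phyABDE lacks all of them but phytochrome C. The titles call the samples of a group biological replicates.

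The deposited table holds linear intensities, 1 value per probe set and array, and the submitters' processing notes name RMA, GCOS and limma without a version or a role for each. The values have the range and the equal spread over arrays of an RMA-type normalization, and medians lay between 40.21 and 44.88 intensity units, so no further normalization was applied. What was done between scan and table beyond this is not given in the sources used here. Values were analysed as log2 of the deposited intensity. The number of arrays limits the precision: the median 95% half-width of a log2 change was 0.30 for red light against dark in either mutant and 0.34 in wild type.

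Of 22810 probe sets, 64 controls were left out and 22746 were tested. A table of GEO's platform annotation names 1 gene for 13513 probe sets and several for 503, and 8730 tested probe sets are unnamed here. Of the probe sets with 1 gene, 13436 matched the RefSeq gene table of assembly TAIR10.1, which was used only for names and for the order of neighbouring genes. Only 1580 carry a symbol other than a locus code. A gene with several probe sets is represented by the brightest.

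The series text says that 5 wild-type arrays (dark replicates 2 to 4 and both red-light arrays) were labelled with the One-cycle kit and the other 17 with the 3' IVT Express kit. The labels of the single samples name the second kit for all 22, so both sources differ, and the series text was followed. Wild-type dark arrays correlated at 0.987 to 0.991 across probe sets within a kit and at 0.978 to 0.982 between kits; these are correlations across probe sets, which are not independent replicates. The linear model held a mean for each of the 8 groups and a term for the kit. With this term the wild-type response to red light rests on the 5 One-cycle arrays, and mutants are set against dark wild type through 1 array, dark replicate 1.

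All 12 comparisons were fitted with limma 3.58.1 (lmFit and eBayes, 13 residual degrees of freedom) in R 4.3.3 over all 22 arrays, with Benjamini-Hochberg adjustment per comparison, and a probe set was called at an adjusted p under 0.05. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The design, the comparisons, 22 gene lists, the rule for named genes and most alternatives were set before the data were examined. Those lists hold 356 genes, of which only 52 have a named probe set: 10 lists could be tested, 7 had 1 or 2 measured members, and 5, among them the phytochromes and the seed reserve genes, had none. Another 14 lists were drawn from the annotated symbols after the table had been opened and before any test. Lists were tested with limma's camera at the preset inter-gene correlation of 0.01, adjusted over 24 lists per comparison, and again with an estimated correlation. List tests of the mutants against wild type in darkness were added to the plan. Of 288 list tests, 81 passed with the preset correlation and 5 of these passed with the estimated one, all 5 being the shade-induced genes.

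The text names, for each light response, the 6 largest rises and 6 largest falls among called probe sets with 1 gene and a symbol whose light and dark arrays did not overlap. The word symbol was read as a symbol other than a locus code. For differences between genotypes it names the 6 largest each way among called probe sets with 1 gene, and in each list at most 4 members. Genes outside this rule are said to have been chosen after their values were seen. An embryo gene level, the mean log2 intensity of 21 genes of seed maturation, was made after the first values were seen, and OLEO3 was left out of it because it fell with red light in wild type.

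Whether equal replicate numbers pair arrays was checked with the correlation of deviations from the group means. In dark and red-light arrays it was 0.33, 0.12 and 0.25 for replicates 1 to 3 of phyABCDE and 0.48, 0.18 and 0.11 for phyABDE, so the numbers were taken as pairs there. The main model held no term for these pairs, so its counts, errors and list tests are unpaired. Pairs entered the fits only as the replicate block among the alternatives. With the block, continuous red light called 0 probe sets in phyABCDE and 35 in phyABDE, 20 of them also called without it. Replicate 3 of phyABDE matched an array of another number better, at 0.18, so its pairing is uncertain. The 2 h groups and wild type under red light have 2 arrays each and were not paired. No 2 arrays of a group held the same values: at most 8 probe sets were identical.

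On data simulated from the real means and spread, 200 probe sets were changed 2-fold or 4-fold, with independent noise in each probe set. The model recovered 86.00% of 2-fold changes for red light against dark in phyABCDE. It recovered 79.00% for 2 h of red light in phyABDE and 88.00% for wild type. Recovery was 53.00% for the difference between the mutants' responses to red light, 84.00% for the mutants in darkness and 68.00% for dark phyABCDE against wild type. Real arrays share noise between genes, which the simulation lacks.

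Alternatives were a model without the kit term, arrays of only the compared groups, the replicate number as a block, the dimmest 33.3% of probe sets left out, quantile normalization, an intensity trend with a robust prior, array weights, offsets of 1 and 16 before the log, a 2-fold minimum, only probe sets with 1 gene, and each array left out in turn. A model of the 16 mutant arrays, the same model with the embryo gene level as a covariate, and a model without both phyABDE arrays of low embryo gene level were added after the data had been seen. Alternatives were computed for the count of each comparison they apply to and each gene value that the text or a plot gives. Called lists were tested again only with the estimated correlation, without the kit term, with the block, with both offsets and with arrays left out. No list was tested with the embryo covariate or the other settings. The overlap of responses was recounted only without the kit term, with the block, both offsets and the 2-fold minimum.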

Results

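The series asks how seedlings with a reduced set of phytochromes respond to red light, and whether phytochrome C, the only phytochrome left in phyABDE, carries a response that phyABCDE lacks. It holds 3 dark arrays, 3 arrays of seedlings kept under red light throughout (R50, a fluence rate of 50 µmol per square metre and second) and 2 arrays of 2 h of red light after darkness (DR2h) for each mutant, and 4 dark and 2 R50 arrays of wild type. Arrays of a group correlated at 0.978 or more across probe sets. The transcripts of the 5 phytochromes, which would check the genotype labels, are not analysed here, because their probe sets are unnamed here.

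In wild type, R50 raised genes of the photosynthetic machinery and lowered genes of shade growth and some genes of cell wall loosening. All 4 measured photosystem subunits rose, among them PSAN by 2.05 ± 0.21 (log2 change ± SE, 2 R50 against 3 dark arrays of one kit) and PSAE-1 by 1.68 ± 0.20. So did 3 of 3 genes of carbon fixation, with SBPASE at 1.56 ± 0.18 and RCA, the RuBisCO activase, at 1.35 ± 0.17. Of 3 antenna genes 2 rose, LHCB4.2 by 2.16 ± 0.30 and LHCB4.1 by 1.41 ± 0.18. All 3 measured shade-induced genes fell. IAA29, an auxin signalling repressor, fell by 2.89 ± 0.18, FHL, a partner of phytochrome A in nuclear import, by 1.95 ± 0.14, and the homeodomain gene HAT2 by 1.76 ± 0.12.

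The 28 nuclear photosynthesis genes, a list added after the table had been opened, held 26 that rose and 1 that fell, with a median of 1.37 (camera adjusted p = 1.7e-17, and adjusted p = 0.088 with an estimated correlation). By description this list covers photosystems and carbon fixation, as do the fixed lists of those names, so here and below they are not separate results. Photosystem subunits had a median of 1.58 (adjusted p = 1.9e-05, and adjusted p = 0.088 with an estimated correlation), carbon fixation 1.35 (adjusted p = 0.0026, and adjusted p = 0.12 with an estimated correlation) and light harvesting 1.41 (adjusted p = 0.007, and adjusted p = 0.18 with an estimated correlation). Adjusted over the list alone, 4 of 4 photosystem, 3 of 3 carbon fixation and 3 of 3 antenna genes rose. Shade-induced genes had a median of -1.95 (adjusted p = 1.0e-05), and this passed with an estimated correlation too (adjusted p = 0.0061), with 3 of 3 falling adjusted over the list alone.

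Photorespiration followed the photosynthetic genes, with 3 of 3 members higher, HPR, a hydroxypyruvate reductase, by 2.02 ± 0.24 (list adjusted p = 0.0081, and adjusted p = 0.12 with an estimated correlation). Of 8 tetrapyrrole genes 6 rose and 1 fell. HEME1 rose by 1.34 ± 0.16 and CHLM by 1.27 ± 0.17, while PORB, which reduces protochlorophyllide in the light, fell by 0.43 ± 0.13 (list adjusted p = 0.0051, and adjusted p = 0.23 with an estimated correlation). PORB lost its call without dark replicate 3 (-0.36) or R50 replicate 2 (-0.37) of wild type, with the block (-0.57) and with only the compared arrays. Of 6 expansin and xyloglucan endotransglucosylase genes on the fixed list 4 fell, among them XTH33 by 2.24 ± 0.17 and EXPA9 by 1.97 ± 0.20 (list adjusted p = 3.0e-04, and adjusted p = 0.12 with an estimated correlation). The wider expansin and XTH family, 27 genes of an added list, did not pass (4 rose and 9 fell, median -0.10, adjusted p = 0.073). Of 7 tubulins 5 fell (adjusted p = 4.1e-04, and adjusted p = 0.12 with an estimated correlation). The stomatal regulators FMA and SPCH rose by 1.68 ± 0.18 and 1.23 ± 0.18 (list of 3, adjusted p = 0.0081, and adjusted p = 0.088 with an estimated correlation). Adjusted over the list alone the counts were 3 higher for photorespiration, 6 higher and 1 lower for tetrapyrroles, 4 lower for cell wall genes and 2 higher for stomatal genes.

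Among lists with 1 or 2 measured members, which were not tested as lists, the light signalling factor HYH rose by 2.05 ± 0.18 and the auxin-conjugating enzyme gene WES1 fell by 1.61 ± 0.18. The root hair expansins EXPA7 and EXPA18 rose by 1.45 ± 0.24 and 1.42 ± 0.31, and the heat shock gene ATHSP22.0 fell by 1.57 ± 0.20. The flavonoid gene DFR rose by 0.80 ± 0.17, and the 4 flavonoid genes had a median of 0.53 that did not pass (adjusted p = 0.12). DFR lost its call without R50 replicate 1 of wild type (0.50) and with the block (0.54).

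Detection calls are not given, so dim levels are not shown to be above background, and changes from or to them are differences of measured values. The largest measured rises with a symbol were those of IQD24 (3.83 ± 0.16, from a dim 3.09 in the One-cycle dark arrays), the thionin THI2.2 (11.7-fold), CaS, a chloroplast calcium sensor (6.70-fold), MSRB6 (5.54-fold), YAB5 (5.27-fold) and PIFI (5.19-fold). The oleosin OLEO3, a seed oil body protein, had the largest fall (33.5-fold, -5.06 ± 0.14), followed by TUB1 (9.18-fold), the pectin methylesterases PME61 (7.80-fold) and ATPMEPCRD (6.95-fold), IAA29 (7.43-fold) and the endoglucanase GH9B8 (7.24-fold). In all, limma called 6245 of 22746 probe sets, 3115 higher and 3130 lower, and 2206 of them changed at least 2-fold. With the replicate number as a block 3797 were called. The 21 embryo genes had a median of 1.29, from -0.51 to 2.46, with 4 called higher, and were not tested as a list. Their mean level was 5.63 under R50 and 4.50 in the One-cycle dark arrays. The actin 3' minus 5' signal was 3.31 and 3.45 under R50 against 3.03 to 3.20 in those dark arrays.

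Under R50, phyABDE showed a small part of the wild-type change. Of the genes with a symbol, scpl35, a carboxypeptidase-like gene, rose by 0.81 ± 0.15 (3 R50 against 3 dark arrays, adjusted p = 0.04) and COR27, a cold- and clock-regulated gene, fell by 1.32 ± 0.24 (adjusted p = 0.035). Named genes with the largest rises, chosen after their values were seen, were AT1G80130 (2.45 ± 0.32), AT2G43550 (1.76 ± 0.30), AT5G38980 (1.54 ± 0.25) and AT1G52000 (1.41 ± 0.21). Of these AT1G80130 kept its call whichever array was left out. The call of scpl35 was lost whichever array of the comparison was left out (0.75 to 0.89), and that of COR27 with each but R50 replicate 1 (-1.24 without R50 replicate 3). Those of AT2G43550 and AT5G38980 were lost without dark replicate 2 or 3 or R50 replicate 2 or 3 (1.68 and 1.58 without dark replicate 3), and that of AT1G52000 without dark replicate 2 or R50 replicate 2 or 3 (1.29 without the last). COR27 lost its call too without the kit term, with the block and with only the compared arrays (-1.32 each) and with an offset of 16 (-1.09). With only the compared arrays or only probe sets with 1 gene scpl35 did (0.81 each). Without both arrays of low embryo level COR27 (-1.45), scpl35 (0.79) and AT5G38980 (1.64) were not called. All 28 nuclear photosynthesis genes had positive values, with a median of 0.32 (adjusted p = 1.7e-09, and adjusted p = 0.33 with an estimated correlation), though none passed alone over all probe sets and 10 rose adjusted over the list alone.

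The shade-induced genes were the list of phyABDE that held under both correlations, with a median of -0.34 (adjusted p = 0.0011, and adjusted p = 0.048 with an estimated correlation). Over all probe sets none of its 3 genes was called, and adjusted over the list alone 3 fell: IAA29 had -0.55 ± 0.17, HAT2 -0.34 ± 0.10 and FHL -0.30 ± 0.12. Photosystem subunits (median 0.44, adjusted p = 0.0027, and adjusted p = 0.33 with an estimated correlation) had 3 higher adjusted over the list alone, and light harvesting (median 0.42, adjusted p = 0.046, and adjusted p = 0.49 with an estimated correlation) had 1. Carbon fixation (median 0.37, adjusted p = 0.037, and adjusted p = 0.4 with an estimated correlation) had 2 and tetrapyrrole genes (median 0.17, adjusted p = 0.044, and adjusted p = 0.51 with an estimated correlation) had 0, with 2635 of all probe sets under an unadjusted p of 0.05 in limma. With the replicate block both last lists missed the threshold (adjusted p = 0.05 and 0.053). Without dark replicate 2, R50 replicate 2 or R50 replicate 3 of phyABDE the calls of light harvesting (0.33, 0.33 and 0.19), carbon fixation (0.29, 0.37 and 0.28) and tetrapyrrole genes (0.11, 0.14 and 0.16) were lost. Light harvesting was lost with an offset of 16 as well (0.38, adjusted p = 0.059).

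The 33 plastid-encoded photosynthesis genes had a median of 0.39 in phyABDE (adjusted p = 1.2e-04, and adjusted p = 0.51 with an estimated correlation). NDH genes had 0.24 (adjusted p = 0.037, and adjusted p = 0.51 with an estimated correlation) and plastid gene expression 0.31 (adjusted p = 0.011, and adjusted p = 0.59 with an estimated correlation). The NDH call was lost without dark replicate 2 (0.19), dark replicate 3 (0.22) or R50 replicate 2 (0.14) of phyABDE and without the kit term. That of plastid gene expression was lost without dark replicate 3 (0.32) or R50 replicate 2 (0.15). In all 33 probe sets were called, 29 higher and 4 lower, 12 at least 2-fold, and 16 of them are unnamed here. Of these 20 were higher and 2 lower in wild type too, against 3.97 and 0.550 for independent lists, and 4 went the opposite way. The 22 shared calls fell to 12 without the kit term and to 6 at a 2-fold minimum. The block gave 35 calls, 20 of them also called in phyABDE without the block, and COR27 was not among them. The count fell to 4, 5, 5 and 6 without dark replicate 2, dark replicate 3, R50 replicate 2 and R50 replicate 3 of phyABDE. Array weights gave 120 calls, and a model of the compared arrays alone gave 13. In R50 replicates 2 and 3, either of which left out ended most calls, the GAPDH 3' minus 5' signal was 0.52 and 0.53, the highest of all arrays, against 0.07 in R50 replicate 1 and 0.12 to 0.18 in darkness. The actin signal was 3.21 and 3.41 against 3.24 in R50 replicate 1. Whether RNA ends bear on the response was not tested. The embryo level was lower under R50 than in darkness for each replicate number (5.21 and 5.80, 7.46 and 8.04, 7.05 and 7.09), with a median of -0.38 over 21 genes and none called.

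**Figure D1:**
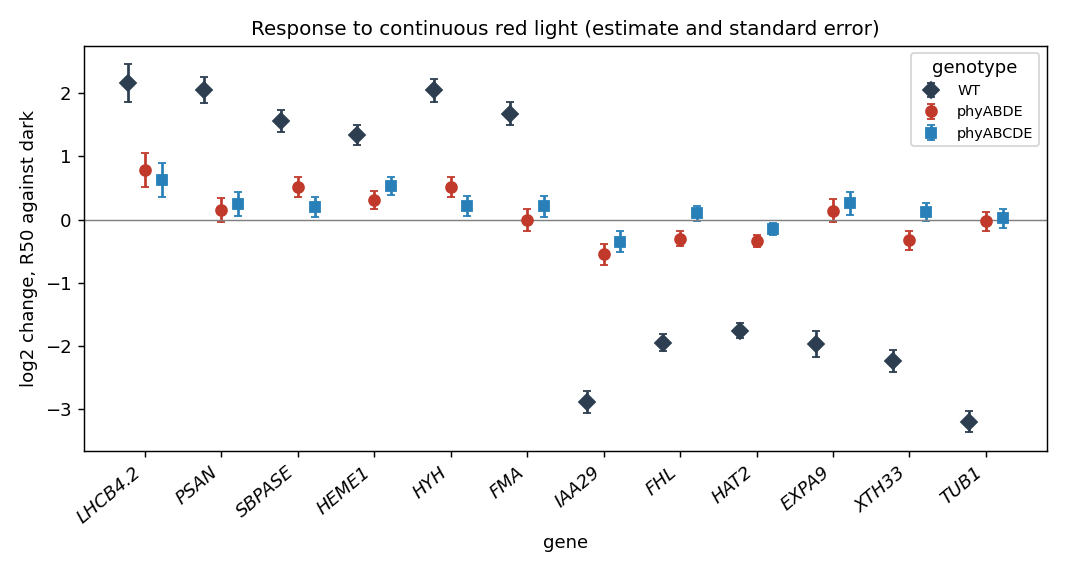
Log2 change of 12 genes under continuous red light against darkness in wild type (diamonds), phyABDE (circles) and phyABCDE (squares), with bars for the standard error of the linear model. The genes were picked for large wild-type changes, from LHCB4.2 at 2.16 to TUB1 at -3.20, and mutant values lie between 0.78 and -0.55, none of them called.

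In phyABCDE, R50 called only 2 probe sets, both higher. AT5G53710 rose by 1.25 ± 0.19 (2.39-fold, adjusted p = 0.033, n = 3 arrays in each group of limma's model), a gene that fell by 1.39 ± 0.21 in wild type. A probe set with several genes rose by 1.62 ± 0.23. In phyABDE AT5G53710 also rose, by 1.01 ± 0.19 (chosen after its values were seen), and both probe sets were among its calls. AT5G53710 lost the call whichever array of the comparison was left out in phyABCDE (1.16 to 1.34) and in phyABDE (0.88 to 1.17). In phyABCDE it lost it too with only the compared arrays and the block (1.25 each), array weights (1.22), an offset of 16 (0.91) and the embryo covariate (1.25). In phyABDE it did with only the compared arrays or probe sets with 1 gene (1.01 each) and without both arrays of low embryo level (0.87).

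Nuclear photosynthesis genes of phyABCDE had a median of 0.24, with 27 of 28 positive (adjusted p = 1.1e-08, and adjusted p = 0.36 with an estimated correlation), 0 called over all probe sets and 1 adjusted over the list alone. Photosystem subunits (median 0.26, adjusted p = 0.0084, and adjusted p = 0.36 with an estimated correlation), light harvesting (0.36, adjusted p = 0.026, and adjusted p = 0.36 with an estimated correlation) and tetrapyrrole genes (0.18, adjusted p = 0.0036, and adjusted p = 0.36 with an estimated correlation) shifted upward too, with 0, 0 and 2 members higher adjusted over the list alone. The autophagy genes had a median of -0.15 (adjusted p = 0.0036, and adjusted p = 0.36 with an estimated correlation) and cell division genes 0.13 (adjusted p = 0.032, and adjusted p = 0.36 with an estimated correlation). Plastid-encoded photosynthesis genes had a median of -0.09 (adjusted p = 0.029, and adjusted p = 0.57 with an estimated correlation), which turned to 0.11 without dark replicate 2 and 0.09 without dark replicate 3 of phyABCDE and lost its call without R50 replicate 1 (-0.08) and without the kit term (adjusted p = 0.071). Without dark replicate 1 the calls of photosystem subunits (0.25), light harvesting (0.36) and tetrapyrrole genes (0.08) were lost, and nuclear photosynthesis genes in phyABCDE R50 vs dark kept theirs at 0.15. Light harvesting lost it too without dark replicate 2 (0.39) or R50 replicate 2 or 3 (0.36 and 0.31). Autophagy genes lost it without dark replicate 3 or R50 replicate 1 (-0.11 each), and cell division genes without dark replicate 3 (0.11) or R50 replicate 2 (0.09). Shade-induced genes did not pass here (median -0.15, adjusted p = 0.17). At an unadjusted p under 0.05 limma gave 1291 of 22746 probe sets, little more than the share of 0.05 that would pass by chance. No call was left with the replicate block, nor without dark replicate 1 or 3 or R50 replicate 1, 2 or 3 of phyABCDE, and 1 was left without dark replicate 2. The embryo level fell in parallel: it was lower under R50 than in darkness for each replicate number (8.25 and 8.85, 7.98 and 8.61, 7.97 and 8.44), with a median of -0.56 over 21 genes and none called. So was the GAPDH 3' minus 5' signal (0.04 and 0.18, 0.22 and 0.43, -0.03 and 0.18).

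**Figure D2:**
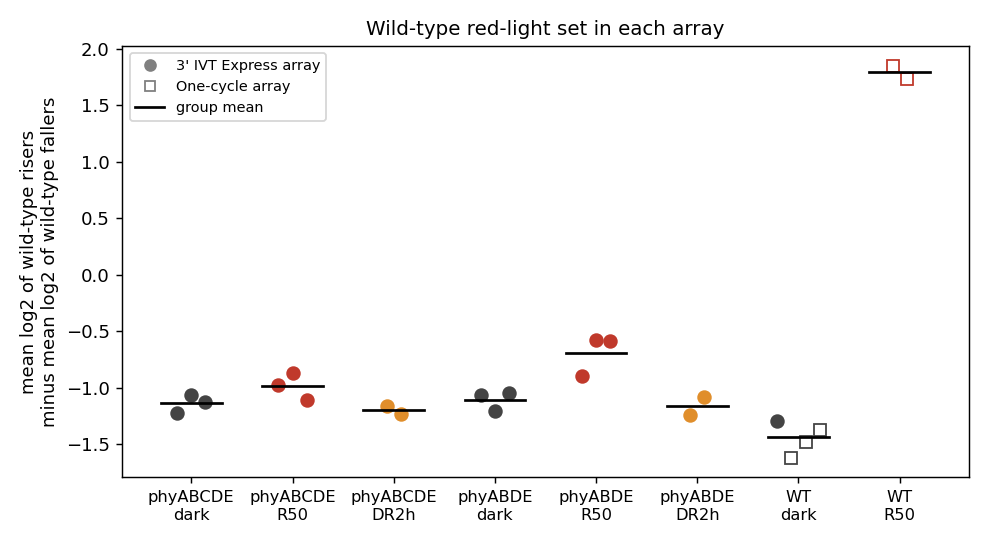
Mean log2 intensity of the 1194 probe sets that rose at least 2-fold in wild type minus that of the 1012 that fell, per array, with a line for each group mean. Wild-type R50 arrays lie at 1.85 and 1.73, phyABDE R50 arrays at -0.90, -0.58 and -0.59, and all other arrays at -0.87 or lower, including those of phyABCDE under R50.

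The wild-type response exceeded that of either mutant in the test of the difference itself. The wild-type response rests on One-cycle arrays and both mutant responses on 3' IVT Express arrays. The kit term removes only a constant shift, so a kit effect on the size of changes cannot be told apart from genotype. IAA29 differed by -2.54 ± 0.25 from phyABCDE and -2.34 ± 0.25 from phyABDE, FHL by -2.06 ± 0.19 and -1.65 ± 0.19, PSAN by 1.81 ± 0.28 and 1.90 ± 0.28, and HYH by 1.83 ± 0.24 and 1.53 ± 0.24. Among all genes with 1 locus the largest difference was that of AT1G22690, 5.58 ± 0.26 from phyABCDE and 5.68 ± 0.26 from phyABDE, and OLEO3 differed by -5.01 ± 0.19 and -5.25 ± 0.19. The shade-induced list differed with a median of -2.06 from phyABCDE (adjusted p = 3.1e-06, and adjusted p = 0.0041 with an estimated correlation) and -1.65 from phyABDE (adjusted p = 3.4e-06, and adjusted p = 0.0042 with an estimated correlation), with 3 of 3 lower adjusted over the list alone in each. In nuclear photosynthesis genes 21 of 28 were higher in each comparison, with medians of 1.07 (adjusted p = 2.4e-13, and adjusted p = 0.13 with an estimated correlation) and 1.01 (adjusted p = 1.1e-13, and adjusted p = 0.13 with an estimated correlation). Adjusted over the list alone 24 and 22 were higher. Limma called 3906 probe sets against phyABCDE, 1882 higher and 2024 lower, and 3097 against phyABDE, 1585 higher and 1512 lower. Embryo genes moved with these comparisons, with a median of 1.80 and 3 of 21 called higher against phyABCDE, and with 2 called and values from -0.13 to 3.15 against phyABDE.

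Among the probe sets that changed at least 2-fold in wild type, 78.5% of 1194 risers had a positive value in phyABDE R50 and 77.3% of 1012 fallers a negative one, with a slope of 0.117 on the wild-type change. In phyABCDE these shares were 74.1% and 54.2% and the slope 0.0445. After 2 h of light they were 52.8% and 38.9% in phyABCDE and 39.0% and 51.4% in phyABDE, with slopes of -0.0109 and -0.0108. The fold changes that chose the set come from wild-type arrays alone, but its adjusted p used the spread of all 22 arrays. The difference between both mutants was tested directly: limma called 0 probe sets for R50 (899 at an unadjusted p under 0.05) and 0 for DR2h (723). Of 22746 unchanged probe sets a share of 0.05 would pass the unadjusted threshold by chance, and both counts lie under that share. The plastid-encoded photosynthesis genes were lower in the R50 response of phyABCDE than in that of phyABDE by a median of 0.56 (median -0.56, adjusted p = 3.1e-08, and adjusted p = 0.71 with an estimated correlation), the NDH genes by 0.43 (median -0.43, adjusted p = 0.0016, and adjusted p = 0.6 with an estimated correlation) and plastid gene expression by 0.38 (median -0.38, adjusted p = 0.0028, and adjusted p = 0.87 with an estimated correlation). Without dark replicate 2, dark replicate 3 or R50 replicate 1 of phyABCDE the calls of NDH genes (-0.21, -0.16 and -0.26) and plastid gene expression (-0.20, -0.17 and -0.15) were lost, the last also without R50 replicate 2 of phyABDE (-0.29). The list of plastid photosynthesis genes in the R50 response of phyABCDE vs phyABDE kept its call, at -0.29 without dark replicate 2, -0.33 without dark replicate 3 and -0.99 without dark replicate 1 of phyABCDE, and -0.35 without dark replicate 2 of phyABDE. The shade-induced genes did not differ between both mutants in this test, with a median of 0.20 for R50 (adjusted p = 0.074) and 0.24 for DR2h (adjusted p = 0.28). Nor did carbon fixation for R50 (-0.13, adjusted p = 0.6). Without dark replicate 3 of phyABCDE, 1 probe set was called for DR2h.

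After 2 h of red light AT5G53710 was the strongest riser in phyABCDE, at 2.37 ± 0.21 (2 DR2h against 3 dark arrays, limma adjusted p = 2.4e-05). The other calls were probe sets unnamed here, with values of 1.09 ± 0.16, 1.07 ± 0.17 and -1.20 ± 0.18. The actin 3' minus 5' signal of phyABCDE was 3.25 and 3.15 in DR2h, below 3.54, 3.80 and 3.26 in darkness, and its bearing was not tested. In phyABDE the only call was AT5G21020, at 1.54 ± 0.18 (2.91-fold, adjusted p = 0.0015), while IAA29 had -1.15 ± 0.18 (adjusted p = 0.068). Shade-induced genes had a median of -0.40 in phyABDE (adjusted p = 4.3e-06, and adjusted p = 0.0053 with an estimated correlation), with 2 of 3 lower adjusted over the list alone, and -0.23 in phyABCDE (adjusted p = 0.013, and adjusted p = 0.07 with an estimated correlation), with 1. The list of shade and PIF targets in phyABDE DR2h vs dark kept its call at -0.22 without DR2h replicate 2 of phyABDE, and in phyABCDE the call was lost without dark replicate 3 of phyABCDE (-0.25) and with the block (-0.24, adjusted p = 0.11). AT5G21020 lost its call without DR2h replicate 2 of phyABDE (1.42), with the block (1.47) and with only the compared arrays (1.54).

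Nuclear photosynthesis genes of phyABDE had a median of -0.23 after 2 h (adjusted p = 4.3e-06, and adjusted p = 0.37 with an estimated correlation), and plastid-encoded photosynthesis genes 0.48 (adjusted p = 1.1e-08, and adjusted p = 0.37 with an estimated correlation). Plastid gene expression had 0.42 (adjusted p = 2.3e-06, and adjusted p = 0.37 with an estimated correlation) and tetrapyrrole genes -0.17 (adjusted p = 0.021, and adjusted p = 0.37 with an estimated correlation). Autophagy genes had 0.13 (adjusted p = 0.021, and adjusted p = 0.48 with an estimated correlation) and dehydration and cold genes 0.31 (adjusted p = 0.021, and adjusted p = 0.37 with an estimated correlation). UDP-glycosyltransferases, which attach sugars to small molecules, had a median of 0.09 in phyABCDE (adjusted p = 0.0018, and adjusted p = 0.07 with an estimated correlation) and 0.02 in phyABDE (adjusted p = 0.033, and adjusted p = 0.37 with an estimated correlation). Of all these lists of phyABDE most rest on 1 array: without DR2h replicate 1 the calls were lost for nuclear photosynthesis (-0.05, adjusted p = 0.57), plastid gene expression (0.14, adjusted p = 0.15), tetrapyrrole (-0.12), autophagy (0.11), dehydration and cold (0.20) and UDP-glycosyltransferase genes (-0.02). Plastid-encoded photosynthesis genes and shade-induced genes kept theirs. Without dark replicate 1 of phyABDE tetrapyrrole (-0.12), autophagy (0.13) and dehydration and cold genes (0.29) lost theirs too. So did UDP-glycosyltransferases without dark replicate 3 (0.04) and autophagy genes without DR2h replicate 2 (0.14), and with the block tetrapyrrole genes (-0.16) and UDP-glycosyltransferases (0.00). The embryo gene level of phyABDE stood at 8.05 ± 0.07 (SD, n = 2) in DR2h and 6.97 ± 1.12 (n = 3) in darkness. Counts were 4 for phyABCDE (3 higher, 1 lower) and 1 for phyABDE. The first fell to 1 when dark replicate 1, dark replicate 2 or either DR2h array of phyABCDE was left out and rose to 26 with the block and 15 with array weights. The second fell to 0 without DR2h replicate 2 of phyABDE, rose to 3 without dark replicate 2 of phyABDE, and was 6 with array weights. The log2 changes under R50 and DR2h share the dark arrays: their correlation over probe sets was 0.50 in phyABCDE and 0.02 in phyABDE, where unchanged groups gave 0.45, with covariances of 0.0197 and 0.000901 against 0.0140. Probe sets are not independent replicates, and the 3 dark arrays could not be halved with 2 left in each part. A likeness of both responses apart from the shared dark arrays was therefore not tested. The simulated correlation lay much further from phyABDE than from phyABCDE, so it is no sure reference, and no excess in phyABCDE is read from it.

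In darkness phyABCDE differed from phyABDE in a set of genes with very large differences. JAL33, a jacalin-related lectin, was 18.1-fold lower in phyABCDE (-4.18 ± 0.17, n = 3 and 3), at 5.91 ± 0.16 (SD) against 10.08 ± 0.19. Wild type lay at 10.27 in dark replicate 1 and 9.99 in the One-cycle arrays. AT5G23830 was higher by 4.15 ± 0.30, at 7.16 ± 0.98 against a dim 3.00 ± 0.12, not shown to be above background, and 3.21 in wild-type dark replicate 1. Other genes higher in phyABCDE were AT5G15420 (2.70 ± 0.25), AT5G38030 (2.64 ± 0.27), AT3G02480 (2.52 ± 0.54), the defensin PDF2.1 (2.48 ± 0.57) and AT1G13340 (2.39 ± 0.52). Genes lower were AT5G16980 (-2.68 ± 0.27), AT5G35940 (-2.56 ± 0.24), AT1G15010 (-1.94 ± 0.38), AT5G19240 (-1.83 ± 0.25) and AT5G52810 (-1.63 ± 0.22). Of these 12 genes 7 lie on chromosome 5. The calls of PDF2.1 and AT1G13340 were lost with only the compared arrays, and those of both and AT3G02480, an embryo gene, with the intensity trend. Left-out arrays ended them too: without dark replicate 1 of phyABDE PDF2.1 had 1.83 and AT1G13340 1.73, and without dark replicate 3 of phyABDE they had 2.60 and 2.33. AT3G02480 lost its call in both cases, with 2.57 in the second. Without dark replicate 1 of phyABCDE PDF2.1 (2.40) and AT1G13340 (2.27) lost the call, and without dark replicate 2 PDF2.1 (2.29) and AT3G02480 (2.47). The other 9 kept their calls whichever array was left out. With an offset of 16 AT3G02480 (2.23) was not called. With the embryo covariate PDF2.1 (0.55), AT1G13340 (0.61), AT3G02480 (2.13) and AT1G15010 (-1.88) were not called.

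Photosynthetic gene lists were lower in dark phyABCDE than in dark phyABDE, and most of these calls rest on dark replicate 1 of phyABCDE. The 28 nuclear genes had a median of -0.30, with 2 called and 8 lower adjusted over the list alone (adjusted p = 9.5e-08, and adjusted p = 0.42 with an estimated correlation), and the 33 plastid-encoded ones -0.60 (adjusted p = 1.6e-07, and adjusted p = 0.42 with an estimated correlation). Photosystem subunits had a median of -0.36 (adjusted p = 0.014, and adjusted p = 0.42 with an estimated correlation) with 3 lower adjusted over the list alone, and light harvesting -0.36 (adjusted p = 0.046, and adjusted p = 0.42 with an estimated correlation) with 1. Tetrapyrrole genes had -0.27 (adjusted p = 0.0038, and adjusted p = 0.42 with an estimated correlation) with 1, and NDH genes -0.40 (adjusted p = 0.014, and adjusted p = 0.42 with an estimated correlation). HEME1, of the tetrapyrrole pathway, was lower (-0.65 ± 0.14), and the heat shock gene AT1G53540 was higher by 1.92 ± 0.35. HEME1 lost its call without dark replicate 1 of phyABCDE (-0.50) or dark replicate 1 or 3 of phyABDE (-0.56 and -0.57), and with only the compared arrays (-0.65). With the embryo covariate HEME1 (-0.45) and AT1G53540 were not called. Plastid gene expression genes had a median of -0.29 (adjusted p = 0.015, and adjusted p = 0.63 with an estimated correlation), which turned to 0.13 without dark replicate 1 of phyABCDE. Without that array the calls of plastid-encoded photosynthesis (-0.13, adjusted p = 0.48), NDH (-0.07, adjusted p = 0.54), photosystem (-0.33), light harvesting (-0.40) and tetrapyrrole genes (-0.19, adjusted p = 0.14 for these last lists) were lost, and nuclear photosynthesis genes kept theirs. Light harvesting lost it too without dark replicate 2 of phyABCDE (-0.37) or dark replicate 1 or 3 of phyABDE (-0.46 and -0.31). Photosystem genes did without dark replicate 3 (-0.29), and NDH and plastid gene expression genes without dark replicate 1 of phyABDE (-0.35 and -0.23) and without the kit term (adjusted p = 0.13 and 0.059). With an offset of 16 light harvesting was lost (-0.35, adjusted p = 0.061). In all 529 probe sets were called, 306 higher and 223 lower, 200 at least 2-fold. Of these 523 had the same sign between both mutants under R50 and 519 under DR2h. The count fell to 245 and 268 without dark replicates 1 and 3 of phyABDE, and to 306 with only the compared arrays. The actin 3' minus 5' signal was 3.54, 3.80 and 3.26 in dark phyABCDE and 3.13, 3.35 and 3.17 in dark phyABDE. Whether this bears on the comparison was not tested. The mean embryo level was 8.63 ± 0.20 in phyABCDE and 6.97 ± 1.12 in phyABDE, with 6 of 21 embryo genes called higher. The model of the 16 mutant arrays called 572 probe sets, and 172 with this level as a covariate.

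**Figure D3:**
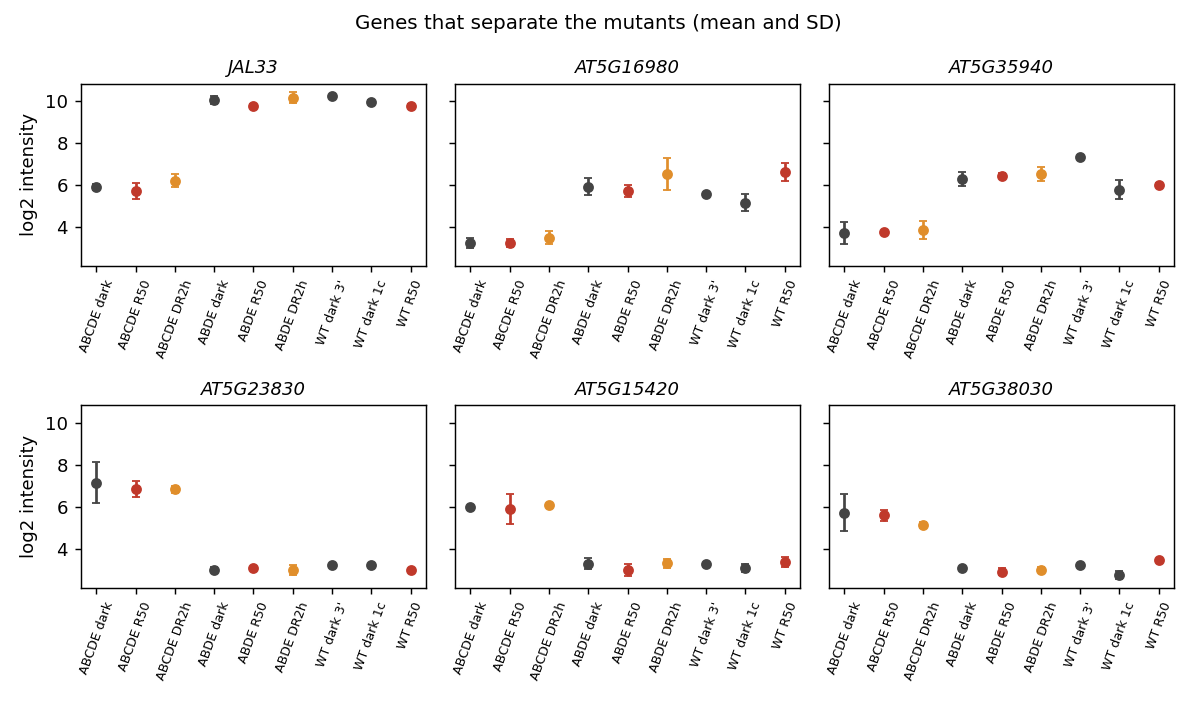
Log2 intensity of genes that separate the dark mutants, as mean and SD per group. They are the 3 most lower (top) and most higher (bottom) in dark phyABCDE than in dark phyABDE among called probe sets with 1 gene. Wild-type dark arrays are split by labelling kit, with no bar where a group has 1 array. For JAL33, phyABCDE lies at 5.91 in darkness and phyABDE at 10.08, beside 10.27 in wild-type dark replicate 1.

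The dark mutants are set against 1 wild-type array, dark replicate 1, whose own spread is unknown: the model takes it to vary like the other arrays, and all p-values and errors against dark wild type rest on that. Seed maturation genes stood higher in phyABCDE than in this array, with 16 of 21 embryo genes called (median 3.77, from -0.17 to 9.59). In phyABDE 2 of 21 were called, M17 and PAP85 (median 1.90, from -2.69 to 8.59). M17 was higher by 9.59 ± 0.99 in phyABCDE and 8.59 ± 0.99 in phyABDE. PAP85, a vicilin-like seed storage protein, was higher by 8.19 (adjusted p = 2.3e-04) and 6.42 (adjusted p = 0.0057). Both genes and the list were chosen after values were seen. The embryo level was 4.84 in wild-type dark replicate 1 and 4.50 ± 0.67 (SD, n = 3) in One-cycle dark arrays. Of the listed genes, phyABCDE had less LHCB4.2 (-1.57 ± 0.38) and HYH (-0.91 ± 0.23). It had more of the stress regulator STZ (1.37 ± 0.31), AT1G53540 (2.46 ± 0.50), ATHSP22.0 (1.32 ± 0.25), the gibberellin receptor GID1A (0.96 ± 0.23) and the glyoxylate cycle enzyme ICL (1.71 ± 0.40). HYH lost its call without the kit term (-0.38), with the block (-0.84), with only the compared arrays, and without dark replicate 1 (-0.84) or 3 (-0.89) of phyABCDE. Without dark replicate 2 of phyABCDE GID1A (0.87), ICL (1.60) and LHCB4.2 (-1.38) lost theirs. GID1A and ICL lost it with only the compared arrays too, and GID1A with the block (0.91).

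Nuclear photosynthesis genes were lower in phyABCDE than in wild type (median -0.26, adjusted p = 9.3e-04, and adjusted p = 0.53 with an estimated correlation), as were photosystem subunits (median -0.59, adjusted p = 0.032, and adjusted p = 0.53 with an estimated correlation), with 2 lower adjusted over the list alone. Without the kit term both lost their calls (-0.19, adjusted p = 0.052, and -0.40, adjusted p = 0.12), and photosystem subunits did without dark replicate 1 of phyABCDE (-0.51). Tetrapyrrole genes were higher in phyABDE than in wild type (median 0.37, adjusted p = 0.0042, and adjusted p = 0.55 with an estimated correlation), with 2 higher adjusted over the list alone. So were plastid-encoded photosynthesis genes (0.34, adjusted p = 0.0042, and adjusted p = 0.61 with an estimated correlation), NDH genes (0.60, adjusted p = 0.0042, and adjusted p = 0.55 with an estimated correlation) and plastid gene expression (0.41, adjusted p = 0.0042, and adjusted p = 0.61 with an estimated correlation). Without the kit term these turned to -0.63, -0.13 and -0.27, the first passing in the opposite direction (adjusted p = 0.0018), and without dark replicate 1 of phyABDE the calls of photosynthesis (0.26) and NDH genes (0.48) were lost. Expansins and XTHs were lower (-0.23, adjusted p = 0.017, and adjusted p = 0.55 with an estimated correlation), a call lost without the kit term (-0.08). In all 819 probe sets were called for phyABCDE (433 higher, 386 lower) and 183 for phyABDE (87 higher, 96 lower). Both rest on dark replicate 1 of wild type, with spread taken from the other arrays: without it no value can be had, and without the kit term the counts were 5562 and 4441. The first fell to 529 without dark replicate 2 of phyABCDE, and the second to 118 and 98 without dark replicates 2 and 3 of phyABDE.

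**Figure D4:**
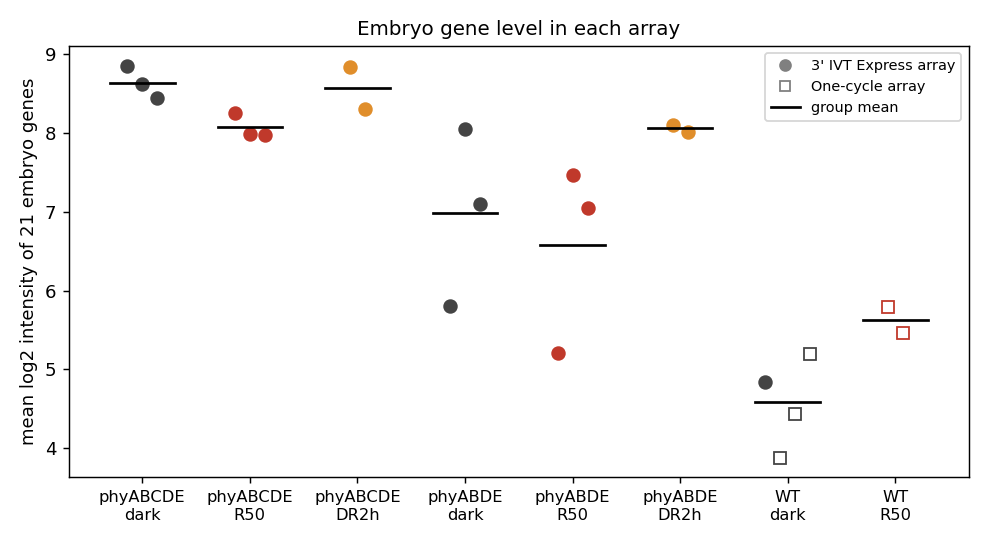
Mean log2 intensity of 21 embryo genes in each array, with a line for each group mean and open squares for One-cycle arrays. The arrays of phyABCDE lie at 7.97 or higher, those of phyABDE in darkness range from 5.80 to 8.04, and wild-type dark arrays lie at 5.20 or lower.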

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

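The model of the 16 mutant arrays with the embryo gene level as a covariate was chosen only after that level had been seen; the simulation was written down before it was read. A measure of RNA ends stood apart in 1 array: the GAPDH 3' minus 5' signal of wild-type dark replicate 2 was -0.05, beside 0.20 to 0.24 in the other dark wild-type arrays. It was 1 of 17 measures examined in this group of 4 arrays, and by chance about 1 in 20 would stand out.

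The response to R50 differed between wild type and phyABCDE in 3906 probe sets. Here and against phyABDE, genotype cannot be told apart from a kit effect on the size of changes. Genes in which wild type went higher were AT1G22690 (5.58), AT3G57020 (5.35), AT5G48490 (5.21), AT4G28780 (4.85), AT3G22060 (4.83) and AT5G38980 (4.29). Genes in which it went lower were OLEO3 (-5.01), AT4G22460 (-4.16), AT4G35720 (-4.14), AT2G34020 (-4.08), AT5G57670 (-4.03) and AT5G02580 (-3.68). Between wild type and phyABDE 3097 probe sets differed. AT1G22690 (5.68), AT3G22060 (4.92), AT3G57020 (4.90), AT4G28780 (4.89), AT5G48490 (4.87) and AT5G43450 (3.92) were higher, and OLEO3 (-5.25), AT4G35720 (-4.39), AT2G34020 (-4.29), AT1G72290 (-4.08), AT5G57670 (-3.91) and AT5G02580 (-3.81) were lower.

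Lists differed between wild type and phyABCDE by these medians: shade-induced genes -2.06, cell wall expansion -1.67, tubulins -0.69, the expansin and XTH family -0.15, photosystem subunits 1.27, carbon fixation 1.12, nuclear photosynthesis genes 1.07, light harvesting 1.05, stomatal markers 1.01 and photorespiration 0.82. Against phyABDE they were -1.65 for shade-induced genes, -1.43 for cell wall expansion, -0.92 for plastid gene expression, -0.61 for tubulins, -0.25 for expansins and XTHs, 1.16 for light harvesting, 1.12 for photosystem subunits, 1.01 for nuclear photosynthesis, 0.99 for carbon fixation, 0.89 for stomatal markers, 0.83 for photorespiration, 0.62 for tetrapyrroles and 0.24 for UDP-glycosyltransferases. The 21 embryo genes, which were not tested as a list, had a median of 1.80 with 3 called against phyABCDE. Against phyABDE 2 of them were called, with values from -0.13 to 3.15. Between both mutants the R50 response differed in plastid-encoded photosynthesis (-0.56), NDH (-0.43) and gene expression genes (-0.38), and the DR2h response in plastid-encoded photosynthesis (-0.31), tetrapyrrole (0.16) and nuclear photosynthesis genes (0.24). Embryo genes, not a tested list, had medians of -0.12 in the first and -1.28 in the second, with none called. All these lists passed with the preset correlation, and of these lists the shade-induced genes passed with the estimated one. Left-out arrays ended calls between wild type and phyABCDE in light harvesting (1.03 without R50 replicate 1 and 0.90 without dark replicate 2 of wild type, 0.99 without R50 replicate 1 and 1.01 without dark replicate 3 of phyABCDE), stomatal markers (1.00 without dark replicate 2 of phyABCDE) and the expansin and XTH family (-0.19 without dark replicate 4 of wild type). Between wild type and phyABDE they did so in light harvesting (1.13 without R50 replicate 1 of wild type, 1.03 without R50 replicate 1 of phyABDE), the expansin and XTH family (-0.23 without dark replicate 4 of wild type) and plastid gene expression (-0.77 without R50 replicate 2 and -0.85 without dark replicate 2 of wild type, -0.70 without R50 replicate 2 of phyABDE). With the replicate block the calls were lost for light harvesting against phyABCDE (1.33, adjusted p = 0.083) and phyABDE (1.43, adjusted p = 0.075), and against phyABDE for the expansin and XTH family (-0.42, adjusted p = 0.06) and UDP-glycosyltransferases (0.10, adjusted p = 0.17). Light harvesting against phyABCDE was lost with an offset of 16 (adjusted p = 0.051), and plastid gene expression against phyABDE without the kit term (-0.67, adjusted p = 0.18). UDP-glycosyltransferases lost the call when any 1 of 6 arrays was left out (0.14 to 0.23). In the DR2h difference of both mutants, plastid-encoded photosynthesis lost its call without the kit term (adjusted p = 0.19), with the block (-0.07) and without dark replicate 2 (-0.06), dark replicate 3 (0.01) or DR2h replicate 2 (-0.19) of phyABCDE, or dark replicate 2 (-0.06), dark replicate 3 (-0.23) or DR2h replicate 1 (-0.16) of phyABDE. Nuclear photosynthesis lost it without DR2h replicate 1 of phyABDE (0.05) or DR2h replicate 2 of phyABCDE (0.14). Tetrapyrroles lost it with the block (0.18) and when any 1 of 6 arrays was left out, the lowest being 0.03 without dark replicate 1 of phyABCDE. The R50 differences of both mutants in NDH and plastid gene expression genes also ended, at -0.16 and -0.17 without dark replicate 3 of phyABCDE.

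Few probe sets were called for R50 in either mutant, and a low number of arrays or uneven embryo content might hide a response. Calls do not count all responding genes. At an unadjusted p under 0.05 limma gave 2635 of 22746 probe sets in phyABDE and 1291 in phyABCDE. Among unchanged probe sets a share of 0.05 would pass by chance. In simulated data with 200 changed probe sets, 86.00% of 2-fold changes were recovered for phyABCDE. This argues against too few arrays only for changes of that size, with independent noise and as many changed probe sets. Smaller shifts, such as median log2 changes of 0.13 and 0.23 over wild-type risers in phyABCDE and phyABDE, were not simulated. With the embryo level as a covariate the calls of both mutants went from 45 to 68, a ratio of 1.51. That is below the ratio of 3 set beforehand for this cause. The calls of phyABCDE fell from 2 to 0 and those of phyABDE rose from 43 to 68. The embryo level was lower under R50 than in darkness for each replicate number of both mutants. The covariate can therefore take up part of the light contrast, so the test cannot decide on this cause. Loss of the phytochromes, which the design names, stays open as the biological explanation and was not tested apart from the genotypes themselves.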

How the results depend on the processing

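The model of the 16 mutant arrays, with or without the embryo covariate, and the one without both phyABDE arrays of low embryo level were chosen after seeing the data. Of 2836 comparisons of called gene values with an alternative, 2632 kept direction and side of the threshold, 204 lost the call and 0 turned (limma). Of 1049 list comparisons 853 kept both, 190 lost the call and 6 turned. Leaving out wild-type dark replicate 1 added 107 of the kept gene values and 33 of the kept lists. With the kit term this array cannot change the wild-type response to R50, so those were fixed in advance. Gene values were mostly picked as the largest calls or list members, so the shares do not speak for other probe sets. The cause of a change was not tested unless said. Without the kit term, R50 called 21 in phyABDE, and dark mutants against wild type 5562 (700 of the calls kept) for phyABCDE and 4441 (159) for phyABDE; the overlap of wild-type and phyABDE responses went from 22 to 12, and plastid gene expression, NDH and photosynthesis genes of dark phyABDE turned to -0.27, -0.13 and -0.63. With only the compared groups the counts were 0 and 13 (R50, phyABCDE and phyABDE), 1 and 0 (DR2h), 306 for dark mutants, 423 and 61 against wild type. The replicate block gave 0 for phyABCDE R50, 3797 for wild type and 26 for phyABCDE DR2h. For R50 against dark within each mutant, where numbers pair arrays, it ended the calls of AT5G53710 and of the probe set with several genes in phyABCDE, and of COR27, carbon fixation and tetrapyrroles in phyABDE, and changed no other reported call there. The DR2h and wild-type numbers share only a number (correlations 0.09 and -0.19, 0.05 and -0.22, 0.15 and 0.08). Leaving out dim probe sets gave 69 for phyABDE R50 and 0 for DR2h, and the trend with a robust prior 59 and 4. Array weights gave 1 and 120 for R50, 15 and 6 for DR2h, and turned the uncalled TUB1 (phyABCDE, -0.02) and FMA (phyABDE, 0.01). An offset of 16 left 0 for phyABCDE R50 and moved dark phyABDE against wild type to 46 higher and 85 lower. A 2-fold minimum, which removes smaller changes by construction, left 12 for phyABDE R50, 2206 for wild type, 2079 and 1722 for wild type against the mutants, 200 for dark mutants, 526 for dark phyABCDE against wild type, and 6 in the overlap. With fewer probe sets, those of 1 gene, counts were 1, 7 and 3180 for R50 in phyABCDE, phyABDE and wild type, 1 and 2 for DR2h, 1923 and 1543 for wild type against the mutants, 287 for dark mutants, 437 and 87 against wild type. The estimated correlation left 5 of 81 lists. The 16 mutant arrays gave 8 and 2 for DR2h and 572 for dark mutants. With the covariate they gave 0 and 68 for R50, 8 and 2 for DR2h and 172 for dark mutants. TUB1 of phyABCDE then had -0.04. Without both low phyABDE arrays, dark counts were 270 between mutants and 341 against wild type, and FMA (0.16) and EXPA9 (-0.03) of phyABDE R50 turned. Leaving out each array gave 0 to 1 for phyABCDE R50 (1 without dark replicate 2), 4 to 46 for phyABDE R50 (without dark replicate 2 and R50 replicate 1), 1 to 5 and 0 to 3 for DR2h in phyABCDE and phyABDE, 0 to 1 for the DR2h difference, 245 to 630 for dark mutants, 529 to 966 and 98 to 246 for dark phyABCDE and phyABDE against wild type. The plastid photosynthesis median of phyABCDE R50 ranged from -0.64 to 0.11 (0.11 without dark replicate 2, 0.09 without 3), that of dark plastid gene expression from -0.64 to 0.13. Uncalled R50 values that turned ranged from -0.02 to 0.24 for XTH33 and -0.08 to 0.10 for TUB1 of phyABCDE, and from -0.13 to 0.09 for FMA (0.06 and 0.04 without dark replicates 1 and 3), -0.02 to 0.31 for PSAN and -0.16 to 0.12 for TUB1 of phyABDE. IAA29 of phyABDE DR2h passed with the trend, with array weights, with 1-gene probe sets and without dark replicate 2 (-1.26). Signal over background is not given, so it was not weighed.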

Other observations

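The tests of embryo content, of the kit and of the chromosome segment were chosen only after the embryo levels and the positions of the differences had been seen. AT5G53710 went up under red light in both mutants and down in wild type. UDP-glycosyltransferases, glutathione transferases and SWEET sugar transporters had 12, 3 and 1 members higher and 6, 2 and 2 lower in wild type under R50, with medians of 0.11, 0.19 and 0.13, and none passed as a list (adjusted p = 0.18, 0.41 and 0.99); for SWEET genes the mean (-0.11) and the test pointed down. The dehydration and cold genes were higher in dark phyABCDE than in wild type, with a median of 0.21, a mean of 1.31 and 3 called (adjusted p = 0.017, and adjusted p = 0.26 with an estimated correlation). That list shares LEA4-5 and AtLEA4-1, higher by 3.21 and 3.26, with the embryo genes, so it is not separate from them. The ER body genes were lower, with a median of -0.42 and 1 of 7 called, JAL33 at -4.36, already named above, the others lying between -0.54 and 0.94 (adjusted p = 0.016, and adjusted p = 0.14 with an estimated correlation), a call lost without the kit term (-0.38).

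Embryo genes were high in phyABCDE and varied between arrays of phyABDE. Seed that had not germinated in the sample stays open as a source: between dark phyABCDE and dark phyABDE the interquartile range over 21 genes was 0.41 around a median of 1.84, with 20 genes higher, but the genes were picked and OLEO3 was left out after levels had been seen, so this cannot support it. Against wild type the differences of phyABCDE were not one amount, from -0.17 to 9.59 around a median of 3.77, and that comparison was not part of the test. Levels in wild-type dark replicate 1 differed between genes, with 2.39 for M17 and 8.53 for AT3G02480. One log2 amount is thus not required there, and this spread cannot decide on seed as a source. The labelling kit was argued against by a range of 3.64 over the 16 mutant arrays of one kit. Delayed growth of the mutants stays open, and so does OLEO3, an embryo gene that lay at 9.07 to 9.55 in every dark array of all genotypes.

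The genes that separate dark phyABCDE from dark phyABDE include AT5G35940 and AT5G38030, which lie near PHYC in the gene order of chromosome 5, the gene in which both lines differ. A segment carried along with the mutation might place such genes there. Of the 200 measured genes nearest to PHYC 10 were called (5.00%, against 2.17% of all). Only 90.6% of windows elsewhere had a lower share, under the 95% set for it, and a window from AT5G16280 to AT5G19930 reached 8.00%. Windows overlap, and those elsewhere may hold other segments that differ between the lines, so the test cannot exclude a segment at PHYC. Embryo content as the source was tested with the embryo level as a covariate, where the share in the window was 2.39 times that of all genes; with 3 called genes its exact interval of 0.310% to 4.32% holds the overall 0.628%, so the test could not decide. The bound set beforehand was a ratio of 2 and was passed; the interval was computed after the ratio had been seen, because 3 genes are too few. Chromosome 5 as a whole had 3.62% of its genes called and the other chromosomes 1.29% to 2.57%, so differences elsewhere on it, from the crosses that made the lines, stay open.

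Other splits of the same arrays were counted for the comparisons with at least 3 arrays per group. With 10 splits of 6 arrays no share under 0.05 can be had: the real split had 2 calls and the highest other 1 for R50 in phyABCDE, 33 and 1 in phyABDE, and 529 and 0 for both mutants in darkness, and in each case 1 split, the real one, gave as many. Among the 4 splits that part every replicate pair, the highest other was 1 for phyABCDE and 0 for phyABDE. For dark mutants against wild type within the newer kit there were 4 splits, too few for such a share, and 1 gave as many: 819 calls and 5 in the highest other for phyABCDE, 183 and 109 for phyABDE. For the difference between the mutants' R50 responses, the real count was 0, which any split reaches (100 of 100 drawn of 200), so this says nothing on chance. The highest other was 751. That split mixed genotypes between light and dark, so it reads the standing difference between both mutants.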
